A study of Homo sapiens with 3 samples.

How the data were processed

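The series holds 3 RNA-seq libraries of teratoma from H1 human embryonic stem cells, numbered as replicates, with 1 deposited table per library. Per the labels' protocols, polyadenylated RNA was made into libraries with a NEBNext Ultra II kit. Bowtie2 and the hg19 genome build are named in the submitters' processing notes, and the version of Bowtie2, the counting tool, read filters, the strand setting and any removal of reads from the host mouse are not given in the sources used here. Reads from mouse tissue that align to the human genome may therefore be part of the values, and antisense or overlapping genes cannot be told apart. The tables have no header. For each of 59443 entries they list a RefSeq transcript, an RPKM value, a length in bases, a read count, a gene symbol with strand, and a last number that appears to be the count of genome placements of the transcript.

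The deposited RPKM values are the authors' reads per kilobase of transcript per 1000000 reads. They equal the deposited read count divided by the length and by 1 total per library, which the values gave as 46243199, 45815402 and 43605458 reads. The deposited counts are raw whole-number reads per transcript. The other deposited columns, the length and the placement number, were the same in all 3 tables and were used only to describe transcripts. Counts summed over transcripts came to 91802175, 90822459 and 90387058, more than the library totals. Some reads were thus counted for more than 1 entry, as would happen for exons shared by several transcripts, though the counting rule is not given. Entries with the same gene symbol were therefore reduced to the entry with the highest mean RPKM, which left 27307 genes and 34327415, 33769090 and 33002916 reads. At the median length of 2500 bases, 1 RPKM corresponds to 116, 115 and 109 reads, and 3 reads to 0.026, 0.026 and 0.028 RPKM. Counting intervals (95%, exact Poisson) and these floors cover counting error only. Genome positions are absent from the tables, and the reference annotation at hand is of another build, so no coordinates were used here. Y-linked genes and XIST, 117 symbols in the annotation, were left out of the gene tables.

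All 3 libraries form 1 group, so no model of differences between groups was fitted. The labels do not say whether the libraries came from separate tumours or animals or from parts of fewer, so the 3 libraries are the units of each SD and test, and the spread between them may be technical. The agreement of each pair of libraries was compared with sampling noise by a chi-square statistic per gene over genes with at least 20 reads. It was 57.7 for teratomas 1 and 2, 313 for 1 and 3 and 233 for 2 and 3, far above the value near 1 that sampling noise alone gives, so no library was a copy of another. Detection meant at least 1 RPKM in all 3 libraries. Levels were compared as log2(RPKM + 1), which understates the differences of low genes. Germ layer markers, the unions of the lists of each layer, were compared within libraries by an exact two-sided sign-flip permutation test over the 3 libraries, with Benjamini-Hochberg adjustment over the 3 pairs of layers. A gene was counted as varying when its highest and lowest library differed by at least 2 on the log2 scale. For each list and library, the mean deviation from the gene's mean over the 3 libraries was set against 10000 random lists of the same size matched on mean expression in 20 bins, and counted when under the 2.5 or over the 97.5 percentile. The common dispersion was estimated from the gene counts with edgeR 4.0.16 in R 4.3.3, as a description of spread.

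The 39 lists hold 409 genes, all of which were measured. The lists, the tests, the thresholds and the rule for named genes were fixed before the data were examined. Named were the 2 members of each list with the highest mean RPKM, POU5F1 and NANOG, the 10 genes with the highest mean RPKM, for each library the 5 genes with the largest excess and the 5 with the largest deficit against the mean of the other two among genes with a mean of at least 5 RPKM, and for each deviating list its 2 members with the largest deviation in the list's direction. Y-linked genes and XIST were excluded from naming, and some genes that the rule takes are not reported here. Alternatives covered the detection level, the pseudocount, a filter on low values, the mean or the sum over entries of a gene, rescaling to 1000000 per library, median-of-ratios scaling, the size of the difference, the matching of random lists and each library left out. Leaving out transcripts under 200 bases was added after the data were seen. Statistics were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. The range and list statistics were tested on counts simulated for the 27307 genes from these libraries. All 100 genes changed 8-fold and all 100 changed 16-fold were recovered, 0 of 27096 unchanged genes were counted as varying, and with no list changed a mean of 5.6 of the 117 list deviations (2 to 12 over 10 simulations) lay outside the central range. The simulated genes were drawn independently, with a dispersion set below the one estimated from these libraries. These rates therefore hold for data with less spread and no co-expression.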

Results

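RNA-seq was available as 3 replicate libraries of teratoma grown from H1 cells, an established line of human embryonic stem cells. A teratoma is a benign tumour in which pluripotent cells differentiate into tissues of the 3 germ layers. Per the labels, 1000000 cells were placed under the skin of SCID-beige mice, an immunodeficient strain, and the tumours were taken after 3 to 4 weeks. The 3 libraries, called teratomas 1, 2 and 3 by their replicate number, formed 1 group with no comparison group. The labels do not say whether they came from separate tumours or from parts of fewer. Library totals were 46243199, 45815402 and 43605458 reads in teratomas 1, 2 and 3. The series title concerns a chromatin landscape of human tissues obtained from teratomas. The comparisons open to these libraries were which lineages left transcripts, how the germ layers compared within a library, and how far the 3 libraries differed. Levels below are RPKM, reads per kilobase of transcript per 1000000 reads, as mean ± SD over the 3 libraries (n = 3) unless values are given per teratoma.

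The most abundant transcripts came from the cytoskeleton, from translation and from neural tissue. ACTG1 and ACTB, the cytoplasmic actins, stood at 2326 ± 48.9 and 1311 ± 19.5 RPKM, and differed little between libraries. TUBA1A, a tubulin abundant in developing neurons, stood at 1600.2 ± 950, and NNAT, an imprinted gene of the developing brain, at 1614 ± 957. The translation factor EEF2 stood at 1018 ± 167, RNR2, the mitochondrial large ribosomal RNA, at 1001 ± 181, and VIM, the intermediate filament of mesenchymal and neural precursor cells, at 955 ± 157. The small RNAs SNORD141A and SNORD141B were listed at 5067 ± 1322 each with the same reads, and MIR3654 at 1531 ± 273. Their annotated lengths were 105, 105 and 56 bases with several genome placements, so these 3 values could not be separated from reads of overlapping or repeated transcripts. Of 27307 genes, 14388 (52.7%) reached 1 RPKM in all 3 teratomas, which is called detected below. The share was 66.5% for genes whose entry with the highest mean RPKM was a protein-coding transcript, and 22.9% where it was a non-coding one. Some protein-coding genes, such as AURKB and OTX2, fell in the latter class.

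Neural markers were widely detected. All 17 genes of the neuron list and all 13 of the neural progenitor list were detected. TUBB3, a tubulin of neurons, stood at 720 ± 431 RPKM and STMN2, a microtubule regulator of growing axons, at 227 ± 185. SOX2 and NES, a transcription factor and an intermediate filament of neural progenitors, stood at 93.8 ± 11.8 and 93.4 ± 5.32, with far smaller spread between libraries than the neuronal genes. Of the 9 neural crest and Schwann cell genes 8 were detected, led by the neurotrophin receptor NGFR (21.4 ± 11.3) and the receptor ERBB3 (20.4 ± 11.7). Of the 7 astroglia genes 4 were detected, led by the gap junction gene GJA1 (49.6 ± 24.5) and the glutamate transporter SLC1A3 (23.5 ± 10.7), and 1 was under 1 RPKM in all 3 libraries. Choroid plexus genes were detected in 5 of 6 cases, led by the thyroid hormone carrier TTR (90.6 ± 77.4), which liver and yolk sac also make, and the water channel AQP1 (10.7 ± 8.16). The remaining choroid plexus gene was under 1 RPKM throughout.

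Other ectoderm lists were patchy. The eye field factors SIX6 (22.3 ± 9.02) and SIX3 (22.1 ± 6.33) were the 2 detected genes of the 8 in the retina list, and 3 members stayed under 1 RPKM in all 3 libraries. No pigment cell gene of 9 was detected, and 6 were under 1 RPKM throughout. The leading members were PMEL, a melanosome protein, at 3.04 ± 2.38, and BEST1, a channel of retinal pigment epithelium, at 1.2 ± 0.272. Epidermis genes were detected in 6 of 14 cases, with 4 under 1 RPKM throughout. The leading members were KRT10 (34.4 ± 35.1) and KRT1 (32.4 ± 44.3), the keratin pair of differentiating epidermis, with an SD as large as the mean.

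Among mesoderm lists, fibroblast and mesenchyme genes were detected in 14 of 15 cases. COL1A1 and COL3A1, fibrillar collagens of connective tissue, stood at 434 ± 288 and 328 ± 185 RPKM. Cartilage genes were detected in 8 of 14 cases, led by the cartilage collagen COL2A1 (85.4 ± 74.1) and the chondrocyte factor SOX9 (39 ± 8.75), with 1 member under 1 RPKM throughout. Smooth muscle and pericyte genes were detected in 6 of 9 cases, led by NOTCH3 (43.8 ± 13.4) and TAGLN (30.5 ± 14.7), with 1 under 1 RPKM throughout. In the kidney and intermediate mesoderm list 6 of 10 were detected and 3 were under 1 RPKM throughout. It was led by the podocyte sialomucin PODXL (25 ± 11.9), which pluripotent cells also make, and the factor LHX1 (21.3 ± 12.3), which neurons also make.

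Muscle, bone, fat and vessel genes were present at lower levels. In the cardiac muscle list 5 of 10 were detected, led by GATA4 (14.6 ± 9.63), a factor shared with endoderm, and the natriuretic peptide gene NPPB (8.02 ± 5.61), with 2 under 1 RPKM throughout. In the skeletal muscle list 3 of 12 were detected and 6 were under 1 RPKM throughout. Its leaders were the skeletal actin ACTA1 (6.46 ± 0.244) and PAX7 (4.33 ± 2.78), a factor of muscle precursors and dorsal neural tube. Bone genes were detected in 3 of 9 cases, led by SPP1 (12.7 ± 8.77) and ALPL (12.4 ± 7.29), and 5 were under 1 RPKM throughout. Adipocyte genes were detected in 3 of 9 cases, led by the lipases LIPE (4.08 ± 0.816) and LPL (2.75 ± 0.0309), and 6 were under 1 RPKM throughout. Endothelium genes were detected in 4 of 12 cases, led by EGFL7 (16.4 ± 7.74) and the tight junction gene CLDN5 (8.37 ± 4.92), with 2 under 1 RPKM throughout. Of the 7 primitive streak genes 2 were detected, MESP1 (3.12 ± 2.29) and EOMES (2.83 ± 0.416), and 2 were under 1 RPKM throughout.

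Blood cell genes were detected in part. Of 10 erythroid genes 6 were detected, led by the alpha globins HBA1 (12.8 ± 8.19) and HBA2 (12 ± 7.36), near-identical copies whose reads could not be told apart, and 3 were under 1 RPKM throughout. Among 11 myeloid leukocyte genes 3 were detected and 4 were under 1 RPKM throughout. CD74, the invariant chain of antigen presentation, stood at 17.1 ± 7.76 and CD68, a lysosomal protein of macrophages, at 6.93 ± 3.36. All 7 lymphocyte genes were under 1 RPKM in each library. The leading lymphocyte genes were CD79A (0.223 ± 0.141) and NKG7 (0.178 ± 0.0787), which rested on 4 to 19 and 4 to 10 reads per library. The level that 3 reads would give at the median transcript length was 0.026, 0.026 and 0.028 RPKM.

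Endoderm was represented by regulators and by secreted products. All 8 endoderm transcription factors were detected, led by FOXA1 (28.4 ± 13.3) and FOXA2 (25.6 ± 13.8), pioneer factors of foregut derivatives. All 14 liver and yolk sac genes were detected, led by the fetal plasma protein AFP (833 ± 926) and the apolipoprotein APOA1 (561 ± 572). Pancreas genes were detected in 10 of 11 cases, led by the enzymes CEL (123 ± 135) and CPA1 (56.8 ± 75.6). Intestine genes were detected in 8 of 12 cases, led by the hindgut factor CDX2 (22 ± 11.6) and the brush border gene VIL1 (19.7 ± 11.4), and 2 were under 1 RPKM throughout. No stomach gene of 7 was detected. TFF1 stood at 6.07 ± 6.47 and CLDN18 at 2.33 ± 2.61, and 3 others were under 1 RPKM throughout. The airway secretoglobin SCGB1A1 (18.2 ± 16.7) was the single detected gene of 7 in the lung list. NKX2-1, a factor of lung, thyroid and forebrain, stood at 1.35 ± 0.873, and 4 lung genes were under 1 RPKM throughout.

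Markers of the starting cells were low. POU5F1 and NANOG, core pluripotency factors, stood at 6.28 ± 4.61 and 0.508 ± 0.0914 RPKM, and POU5F1 had 7 genome placements and retrocopies that could share its reads. LIN28A (17.3 ± 12.4) and DNMT3B (7.44 ± 1.7), which differentiating precursors also make, led the pluripotent stem cell list, of which 7 of 12 were detected and 3 were under 1 RPKM throughout. Of 8 germ cell genes NANOS3 (2.24 ± 0.762) alone was detected, followed by SYCP3 (0.696 ± 0.0612), and 7 were under 1 RPKM throughout. No trophoblast gene of 8 was detected. VGLL1 stood at 2.09 ± 1.4 and XAGE2 at 0.102 ± 0.101, the latter on 6, 3 and 0 reads, and 7 members were under 1 RPKM throughout. Ciliated cell genes were detected in 5 of 10 cases, led by the ciliogenesis factor FOXJ1 (22.5 ± 5.41) and ZMYND10 (8 ± 1.61), with 4 under 1 RPKM throughout.

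HOX genes, which mark position along the body axis, were detected across the clusters. The counts were 8 of 12 anterior, 14 of 15 central and 8 of 12 posterior genes. The anterior list was led by HOXB2 (15.7 ± 4.21) and HOXB3 (13.7 ± 4.82), and 3 of its members were under 1 RPKM throughout. The central list was led by HOXB9 (25.1 ± 16) and HOXB8 (24.7 ± 17.9), and the posterior list by HOXD11 (17 ± 8.84) and HOXC10 (14.4 ± 8.8). All 11 proliferation genes were detected, led by PCNA (51.7 ± 14.5) and TYMS (41.7 ± 16.9), both of DNA synthesis. Hypoxia genes were detected in 7 of 8 cases, led by VEGFA (44.5 ± 8.2) and NDRG1 (39.3 ± 17.3). Immediate early genes were detected in 8 of 9 cases, led by JUN (86.9 ± 34.9) and the heat shock gene HSPA1A (74.8 ± 8.99), which has near-identical copies. All 10 housekeeping and all 17 chromatin regulator genes were detected. EEF1A1 stood at 934 ± 215 beside ACTB, and SMARCA4, a chromatin remodelling ATPase, and RAD21, a cohesin subunit, stood at 78.5 ± 9 and 46.3 ± 4.49.

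At least 50% of the members were detected in 25 of the 39 lists. All members were detected in 7 lists and none in 4, the pigment cell, lymphocyte, stomach and trophoblast lists. With detection set at 5 RPKM, 9 lists had at least 50% of members detected and 8532 genes were detected.

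**Figure D1:**
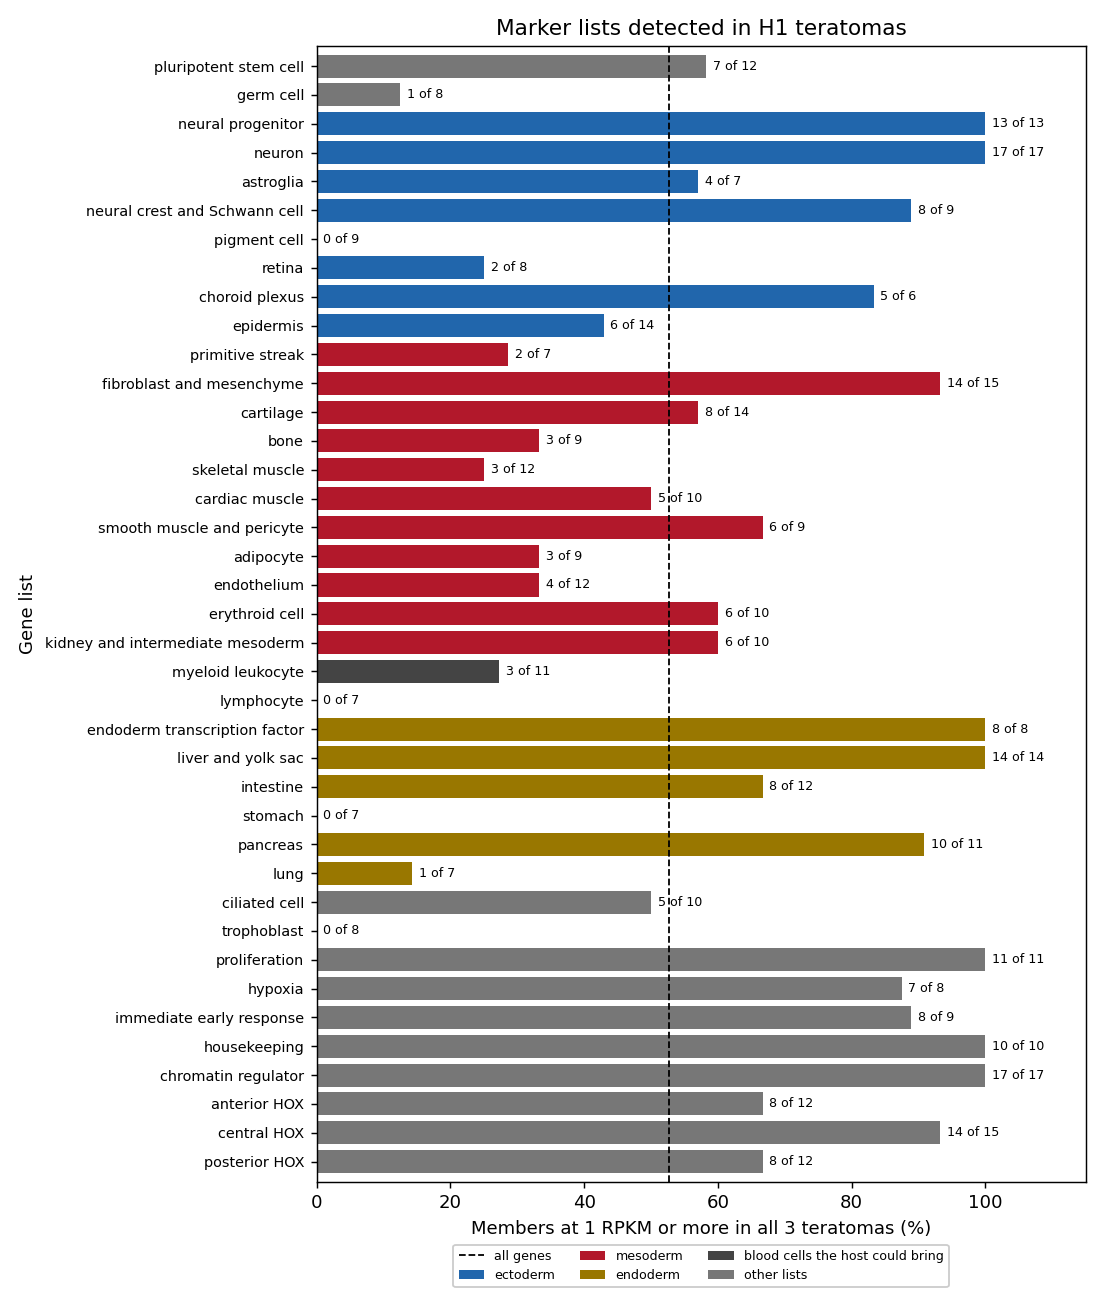
Bars give the percentage of each list's members at 1 RPKM or more in all 3 teratomas, coloured by germ layer, with the number detected of the number measured beside each bar. The dashed line marks the share over all genes, 52.7%, and all members were detected in 7 lists, among them neuron (17 of 17), neural progenitor (13 of 13) and liver and yolk sac (14 of 14).

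Within each library, markers of all germ layers were present, and mesoderm markers were the least often detected and the lowest. This order depends on which genes the lists hold, so it does not give the share of each layer in the tumours. The mesoderm lists include fibroblast, endothelium and erythroid genes, whose cell types the host mouse could also bring. The 59 endoderm markers, such as AFP, FOXA2 and CDX2, reached 1 RPKM in 78.5% ± 8.01 of cases. The 83 ectoderm markers, such as TUBB3, SOX2 and KRT10, did so in 74.3% ± 2.51, and the 117 mesoderm markers, such as COL1A1, GATA4 and HBA1, in 63.8% ± 7.94 (SD, n = 3). Mesoderm lay below endoderm in each library, with mesoderm minus endoderm at -15.5, -13.8 and -14.8 percentage points in teratomas 1, 2 and 3 (mean -14.7 ± 0.843). It lay below ectoderm in 3 of 3 libraries as well (ectoderm minus mesoderm, 10.5 ± 6.71 points). Mesoderm also had the lowest median in each library, with mesoderm at 2.71, 2.92 and 1.24 RPKM, ectoderm at 6.28, 10.3 and 7.59, and endoderm at 12.8, 12.7 and 3.03. On the log2(RPKM + 1) scale the median of ectoderm exceeded that of mesoderm by 1.48 ± 0.48, and mesoderm minus endoderm was -1.52 ± 0.58. Each of these 4 differences had an exact two-sided sign-flip p of 0.25, the smallest that 3 libraries allow, and a Benjamini-Hochberg adjusted p of 0.375 over the 3 pairs, so none passed a test. Ectoderm and endoderm could not be ordered: the share differed by -4.23 ± 7.02 points (ectoderm minus endoderm, higher in 1 of 3, exact p = 0.5, adjusted 0.5) and the median by -0.04 ± 1.03 (exact p = 1, adjusted 1). The sign of that median difference turned without teratoma 1 (0.41), without teratoma 2 (0.08), with a mean of at least 1 RPKM (0.24) or with entries of a gene summed (0.12), and that of the share with detection at 0.1 RPKM (2.14) or with entries summed (1.87). The means of the 4 differences from mesoderm kept their sign in each alternative but not their size: mesoderm minus endoderm was -0.657 (exact p 0.75, so not of 1 sign in all libraries), -7.57 and -22.3 points with detection at 0.1, 0.5 and 5 RPKM, -8.72 with entries of a gene summed and -4.97 after rescaling to 1000000 per library, and its median -0.86 with a mean of at least 1 RPKM. Ectoderm minus mesoderm was 2.79 points at 0.1 RPKM and 4.57 after rescaling, where the exact p was 0.5, 18.95 at 5 RPKM, and 6.93 without teratoma 3.

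The 3 libraries were alike over most genes, and teratoma 3 stood farthest from the others. The correlation of log2(RPKM + 1) across genes, which are not independent replicates, was 0.987 between teratomas 1 and 2 (Spearman 0.98), 0.95 between 1 and 3 (0.954) and 0.962 between 2 and 3 (0.963). The median gene detected in all 3 had an SD of 0.22 on that scale. Differences of at least 2 between the highest and the lowest library were found for 416 genes, and for 415 of them the 95% counting intervals of those libraries lay apart. The number depended on the scale: it was 946 after rescaling to 1000000 per library, and 1704 and 4162 with pseudocounts of 0.1 and 0.01. Teratoma 3 was the lowest for 261 of the 416, teratoma 1 for 146 and teratoma 2 for 9. Between teratomas 1 and 2 alone 56 genes differed that far, between 2 and 3 130, and between 1 and 3 312. The edgeR estimate of the biological coefficient of variation was 36.6% over the 3 libraries and 21.6% over teratomas 1 and 2 alone.

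Teratoma 3 was higher in neuronal transcripts. All 17 neuron genes exceeded their 3-library mean there, by 1.06 on average on the log2 scale. GAP43, a growth cone protein, stood at 66.2, 68.1 and 254 RPKM in teratomas 1, 2 and 3, NEFL, a neurofilament, at 26.4, 43.5 and 132, and STMN2 at 103, 137 and 440. MAP2, a dendritic protein, stood at 32, 56.8 and 143. The 13 neural progenitor genes also lay higher in teratoma 3 (mean deviation 0.39), with FABP7 of radial glia at 34.3, 48.8 and 134, PAX6 at 4.22, 9.21 and 13.8, and NEUROG2 at 4.57, 10.3 and 14.4, while EMX2 (2.33, 1.54 and 3.98) and LHX2 (7.85, 4.7 and 13.3) were lowest in teratoma 2. Among all genes with a mean of at least 5 RPKM, the largest excesses in teratoma 3 included SNCB, a synuclein (2.07, 5.15 and 30.6), MT3, a brain metallothionein (1.78, 3.64 and 17.2), HPCAL4 (1.64, 3.36 and 16) and PPP2R2C (1.52, 4.94 and 18.1). NRN1, a neuritin, stood at 9.41, 9.23 and 44.5. The astroglia list was lower in teratoma 1 (-0.3, 4 of 7 members), with GFAP at 0.392, 2.53 and 4.09 and SLC1A2 at 2.77, 5.07 and 14, while S100B, at 10.1, 4.71 and 3.84, was highest there. The list came within the range of random lists without teratoma 2 (-0.21). Without teratoma 3 the neuron list was higher in teratoma 2 than in teratoma 1 (deviation 0.21 in teratoma 2, against -0.32 with all 3), and the neural progenitor list no longer differed (0.0038 in teratoma 1, against -0.19).

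Connective tissue, vessel and gut transcripts were lower in teratoma 3. In the fibroblast and mesenchyme list 14 of 15 genes lay below their mean there (mean deviation -1.01), with COL1A1 at 699, 475 and 128 RPKM, COL3A1 at 427, 443 and 114, and FN1, fibronectin, at 240, 268 and 55.3. POSTN (52.8, 29.9 and 10.7) and the mesenchymal factor TWIST1 (28.7, 12.6 and 5.89) were highest in teratoma 1. All 12 endothelium genes were lower in teratoma 3 (-0.75), among them CLDN5 (12.1, 10.3 and 2.79), the cadherin CDH5 (4.45, 5.14 and 0.913), ESAM (5.59, 5.31 and 1.19) and the VEGF receptor KDR (2.82, 4.58 and 1.13). So were all 9 smooth muscle and pericyte genes (-0.72), with ACTA2 at 13.6, 26.7 and 6.1, TAGLN at 40.5, 37.4 and 13.7, and MYLK at 3.8, 7.66 and 1.47. All 8 endoderm transcription factors were lower there (-1.05), with HHEX at 12.8, 6.12 and 1.84, FOXA2 at 36.4, 30.2 and 10.1, FOXA3 at 6.55, 6.64 and 1.2, HNF4A at 14.5, 24.2 and 5.2 and SOX17 at 9, 17.8 and 4.07. All 12 intestine genes were lower (-0.85), with the fatty acid binding protein FABP1 at 17.6, 34.9 and 4.97, LGALS4 at 6.36, 7.12 and 0.753 and VIL1 at 28.3, 24 and 6.72. Of 7 stomach genes 6 were lower (-0.61), with TFF1 at 4.4, 13.2 and 0.606, CLDN18 at 5.27, 1.47 and 0.253, TFF2 at 1.38, 2.69 and 0.292, and MUC5AC at 1.5, 0.773 and 0.189. Teratomas 1 and 2 both lay above the mean in the mesenchyme, endothelium, endoderm factor, intestine and stomach lists. Without teratoma 3 they cannot both do so, since the deviations of 2 libraries are equal and opposite. The lower of them then stood at -0.21 for mesenchyme (teratoma 2) and -0.012 for stomach (teratoma 2). For endothelium, endoderm factors and intestine it was teratoma 1, at -0.050, -0.025 and -0.078.

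Teratoma 1 was higher in pancreatic and cartilage transcripts. All 11 pancreas genes exceeded their mean there, by 1.63 on average, and all 11 lay below it in teratoma 3 (-1.42). INS, insulin, stood at 59.5, 4.37 and 0.789 RPKM, a 75.4-fold range with 16 reads in the lowest library, and its transcript overlaps those of the IGF2 region. The acinar enzymes followed, with CPA1 at 144, 19.5 and 7.03, CEL at 275, 78.9 and 15.9, PRSS1 at 107, 23.1 and 4.77 and CELA3B at 21.5, 3.59 and 0.599, the last 2 with paralogs that could share reads. PTF1A, the acinar factor, stood at 25.8, 3.72 and 2.34, and the hormone gene SST at 101, 16.5 and 39.8. All 14 cartilage genes were higher in teratoma 1 (1.03) and lower in teratoma 3 (-1.03), with the matrilin MATN4 at 27.4, 2.92 and 0.672, COL2A1 at 166, 68.9 and 20.9, and COL11A2, which had 7 genome placements, at 16.5, 6.37 and 0.967. The bone list followed at smaller size (0.3 and -0.34, 7 of 9 members each), with SPP1 at 22.5, 10.3 and 5.47, ALPL at 12.2, 19.9 and 5.28, and RUNX2 at 1.47, 0.675 and 0.219. The lung list did so too (0.39, 5 of 7 members with a median of 0.044, and -0.53, 6 of 7), through SCGB1A1 (35.1, 17.7 and 1.83) and SCGB3A2 (2.63, 0.379 and 0.0885). Neural crest and Schwann cell genes were higher in teratoma 1 (0.35, 7 of 9 members), with the crest and glial factor SOX10 at 21.6, 11.3 and 3.99. The kidney progenitor factor SIX2 stood at 11.8, 3.37 and 5.89. Without teratoma 1 the pancreas list in teratoma 2 turned from -0.21 to 0.61.

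Teratoma 2 was higher in liver or yolk sac, epidermal and posterior transcripts. All 14 liver and yolk sac genes exceeded their mean there, by 1.84 on average, and all 14 lay below it in teratoma 3 (-1.6). AFP stood at 452, 1889 and 159 RPKM, AHSG, fetuin A, at 24.9, 266 and 12.3, RBP4, the retinol carrier, at 24, 160 and 14.1, and AMBP at 45.8, 56.6 and 5.19. The apolipoproteins APOA1 (371, 1205 and 109), APOA2 (48.3, 285 and 16.5), APOA4 (43.8, 398 and 26.4) and APOC3 (14.4, 111 and 5.51) followed, with reads of any antisense transcript not separable. The choroid plexus list was higher than its mean in teratoma 2 (0.59, 5 of 6 members) and lower in teratoma 3 (-0.85, 6 of 6), with TTR at 73, 175 and 23.5, AQP1 at 8.42, 19.7 and 3.87 and CLIC6 at 8.38, 8.59 and 1.69. Between teratomas 1 and 2 the difference rested mainly on TTR and AQP1. ENPP2 stood at 10.8, 11.9 and 5.79, while FOLR1 (6.41, 5.22 and 2.52) and KCNJ13 (0.487, 0.259 and 0.15) were highest in teratoma 1. In the epidermis list 13 of 14 genes were higher in teratoma 2 (1.11). KRT1 stood at 0.0794, 83 and 14.3, on 9, 9317 and 1524 reads, KRT5 of basal keratinocytes at 4.14, 54.1 and 9.95, KRT10 at 10.2, 74.7 and 18.3 and SFN at 3.67, 13.2 and 2.04. KRT13, a keratin of mucosal epithelia, stood at 1.84, 23.8 and 6.68, and PERP at 21.9, 26.1 and 7.24. Without teratoma 2 the epidermis list in teratoma 3 turned from -0.38 to 0.17 (it was also within the range of random lists with a pseudocount of 0.01), and the liver and yolk sac list in teratoma 1 from -0.24 to 0.68.

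HOX genes separated teratoma 1 from teratoma 2. All 12 posterior and all 15 central HOX genes were lower than their mean in teratoma 1 (mean deviations -0.86 and -0.73) and higher in teratoma 2 (0.68 and 0.63). HOXC12 stood at 0.5, 23.7 and 12.8 RPKM, HOXC10 at 4.22, 20 and 18.9, HOXD13 at 0.966, 3.73 and 1.08, HOXB8 at 6.9, 42.7 and 24.5 and HOXB9 at 8.28, 40.1 and 26.9. The 12 anterior HOX genes were higher in teratoma 2 (0.36), with HOXC4 at 5.28, 14.3 and 10.3, HOXD3 at 2.64, 7.35 and 5.14 and HOXD4 at 2.07, 6.23 and 3.63. Their deviation in teratoma 1 (-0.19, 7 of 12 members) shrank to -0.0055 without teratoma 2 and lay within the range of random lists with smaller pseudocounts or after rescaling. All 12 pluripotent stem cell genes were higher in teratoma 2 (0.47) and lower in teratoma 1 (-0.3), with POU5F1 at 1.86, 11.1 and 5.93, LIN28A at 11.2, 31.6 and 9.14 and UTF1 at 0.785, 2.51 and 1.78. Without teratoma 2 the deviation of this list in teratoma 1 was -0.06, within the range of random lists.

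Muscle, blood and cell state lists deviated as well. The erythroid list was higher in teratoma 2 (0.65) and lower in teratoma 3 (-0.56), by 8 of 10 members each, with HBZ, an embryonic globin, at 1.17, 5.11 and 0.273 RPKM, HBG2, a fetal globin with a near-identical copy, at 2.04, 5.95 and 1.34, and HBA1 at 11.6, 21.6 and 5.37. The cardiac list was lower in teratoma 3 (-0.47, 7 of 10 members), with NPPB at 8.18, 13.5 and 2.33 and GATA4 at 21.7, 18.6 and 3.65. Its mean deviation of 0.3 in teratoma 2 was not shared by most members: the median was 0.013, 5 of 10 were higher, and HAND1 stood at 1.87, 13.5 and 1.24 while NKX2-5 (2.33, 1.4 and 1.51) and GATA4 were highest in teratoma 1. The skeletal muscle list was lower in teratoma 2 (-0.29, 10 of 12 members) and higher in teratoma 3 (0.36, 12 of 12), with the myogenic factors MYOG at 1.65, 0.114 and 3.55 and MYOD1 at 1.26, 0.0604 and 1.37, and PAX7 at 1.53, 4.35 and 7.09. The pigment cell list was higher in teratoma 2 (0.3, 7 of 9 members), with PMEL at 2.82, 5.53 and 0.79 and TYRP1 at 0.248, 2.12 and 0.231, and the retina list was lower there (-0.15, 5 of 8 members), with SIX6 at 32.2, 14.6 and 20 and SIX3 at 22.9, 15.5 and 28.1. Proliferation genes were higher in teratoma 1 (0.38) and lower in teratoma 3 (-0.52), by 11 of 11 members each, with the kinase AURKB at 24.3, 16.9 and 10.3 and TYMS at 57.7, 43.3 and 24. Immediate early genes did likewise (0.42 and -0.49, 8 of 9 each), with EGR1 at 23, 11.8 and 7.13, JUNB at 20.8, 15.1 and 7.17 and FOS at 19.4, 15.7 and 6.28. Myeloid genes did so as well (0.28 and -0.39, 10 of 11 each), with CD74 at 24.4, 17.9 and 8.94, LYZ at 4.14, 3.92 and 1.16 and SPI1 at 3.16, 1.94 and 0.947. Hypoxia genes were lower in teratoma 1 (-0.31, 7 of 8 members) and higher in teratoma 3 (0.28, 6 of 8), with BNIP3 at 16.3, 21.1 and 41.8 and PDK1 at 6.49, 9.08 and 22.2, while NDRG1 (38, 57.2 and 22.7) and ADM (10.7, 16.5 and 10.5) were lowest in teratoma 3. The trophoblast list lay barely outside the range in teratoma 3 (-0.12, 5 of 8 members, percentile 2.13), with VGLL1 at 3.52, 2.03 and 0.717. It lay within the range, at percentiles from 2.65 to 23.4, with entries of a gene averaged or summed, a pseudocount of 0.01, a mean of at least 1 RPKM, unmatched random lists or short transcripts left out. Cardiac and pigment cell genes in teratoma 2 also came within it, the former with a pseudocount of 0.01 and the latter with a mean of at least 1 RPKM, and so did retina genes with either smaller pseudocount or after rescaling. MIR1234, among the largest deficits of teratoma 2 by rank, rested on 10, 1 and 6 reads. With a library left out, some of these deviations came within the range of random lists: cardiac (0.067 in teratoma 2), myeloid (0.087) and proliferation genes (0.12, both in teratoma 1) without teratoma 3, and hypoxia (0.13) and trophoblast genes (-0.073, both in teratoma 3) and retina genes (-0.11 in teratoma 2) without teratoma 1.

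Over 39 lists and 3 libraries, 67 of the 117 list deviations lay outside the central range of random lists matched on expression, where chance gives 5.85. They involved 31 lists, with 13 higher and 10 lower in teratoma 1, 16 and 5 in teratoma 2, and 4 and 19 in teratoma 3. The germ cell, primitive streak, adipocyte, kidney and intermediate mesoderm, lymphocyte, ciliated cell, housekeeping and chromatin regulator lists stayed within that range in all 3 libraries. Co-expressed genes widen the true spread, so these percentiles describe the libraries and are no p-values. Without teratoma 3, when each list deviates by equal and opposite amounts in teratomas 1 and 2, 44 list deviations lay outside the range, out of fewer than 117.

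**Figure D2:**
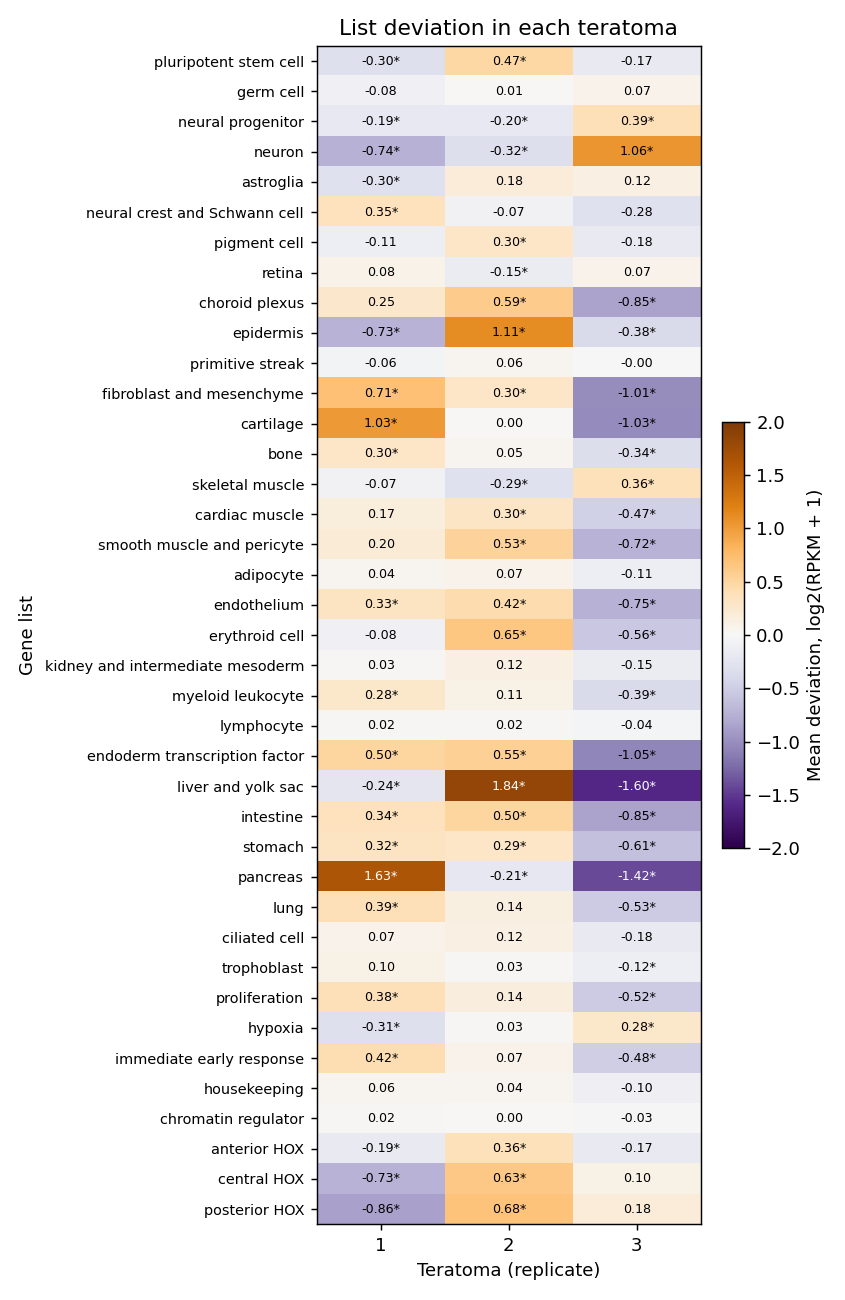
Colour and numbers give the mean deviation of each list in each teratoma from the mean of the 3, on the log2(RPKM + 1) scale, and asterisks mark deviations outside the central range of random lists matched on expression. The neuron list stands at 1.06 in teratoma 3, the pancreas list at 1.63 in teratoma 1 and the liver and yolk sac list at 1.84 in teratoma 2.

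**Figure D3:**
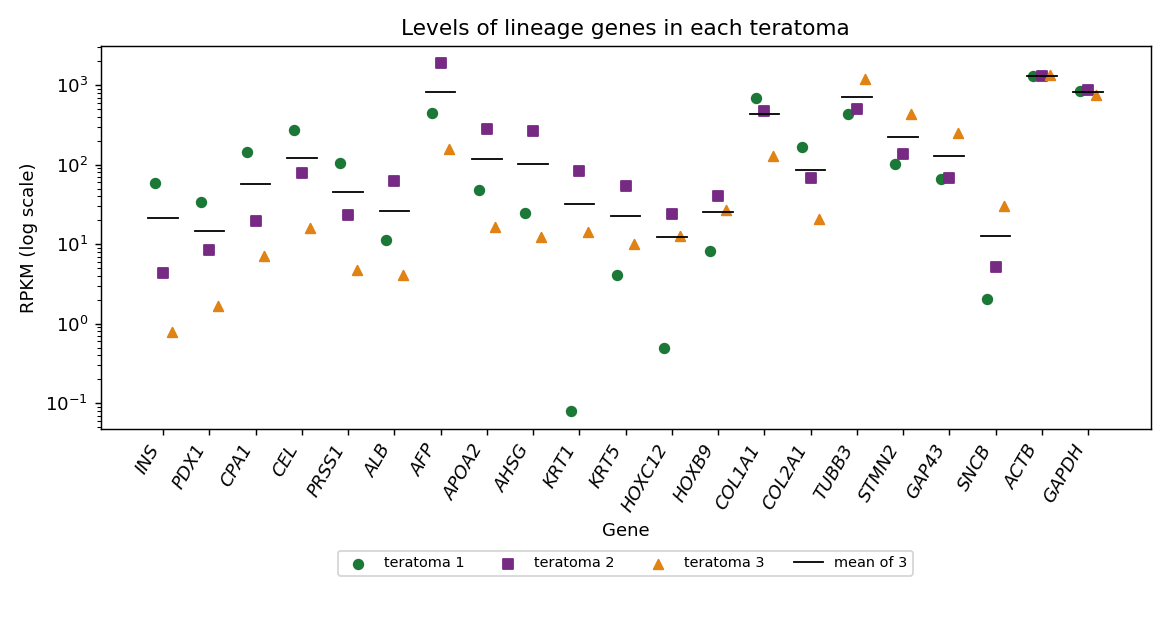
Points give RPKM on a log axis for lineage genes in teratomas 1, 2 and 3, and horizontal lines their mean. INS ranges from 0.789 to 59.5 RPKM and KRT1 from 0.0794 to 83, while ACTB stays between 1290.5 and 1329.6.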

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

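The alternative without transcripts under 200 bases was chosen after the results were seen, and all others before. Of 119 alternative values of the main results, 101 were counted as the same, 12 moved and 6 turned sign. Differences between germ layers were judged by sign alone, so a change in their size was not counted as moved. Of 269 values of the genes named for their excess or deficit in a library, 1 moved and 0 turned. These genes were picked as the most extreme, so a turn was unlikely, and other named genes were not included. No alternative of the germ layer tests could reach a p under 0.25. Ectoderm minus endoderm turned from -4.23 to 2.14 points with detection at 0.1 RPKM and to 1.87 with entries of a gene summed. Its median turned from -0.04 to 0.12 with summed entries, to 0.24 with a mean of at least 1 RPKM, and ranged from -0.60 to 0.41 with each library left out (0.08 without teratoma 2). With detection at 5 RPKM there were 8532 detected genes in place of 14388 and 9 lists in place of 25, fewer by construction. Varying genes numbered 416, and 946 after rescaling to 1000000, 1704 and 4162 with pseudocounts of 0.1 and 0.01, 3303 and 52 with differences of 1 and 3, and 56 (without teratoma 3) to 312 (without teratoma 2), with 130 without teratoma 1. Shifts from scaling were taken as the median over genes whose mean log2(RPKM + 1) was at least 1. Rescaling to 1000000 raised these genes by a median of 1.63 to 1.72, so low genes lost less to the pseudocount. Median-of-ratios scaling moved them by a median of -0.04 to 0.05 and kept 67 of 67 list calls. The lowest correlation between libraries was 0.95, and 0.872 with a mean of at least 1 RPKM, where genes near 0 no longer enter; it ranged from 0.95 to 0.987 with each library left out. List calls numbered 67 of 117, and 44 to 52 with each library left out. With 2 libraries fewer list and library pairs exist, so the lower numbers alone do not show a weaker pattern. The retina list in teratoma 2 turned to 0.0028 with a pseudocount of 0.01, and the cause was not tested. Some deviations turned when a library was left out, by construction since they are relative to the mean. In teratoma 2 these ranged, without teratoma 1 and without teratoma 3, from -0.69 to 0.21 for neuron, 0.65 to -0.21 for mesenchyme, 0.45 to -0.012 for stomach and 0.61 to -0.92 for pancreas. In teratoma 1, without teratoma 2 and without teratoma 3, they ranged from -0.29 to 0.0038 for neural progenitor, 0.54 to -0.050 for endothelium, 0.78 to -0.025 for endoderm factors, 0.60 to -0.078 for intestine and 0.68 to -1.04 for liver and yolk sac. For epidermis in teratoma 3 they were -0.75 without teratoma 1 and 0.17 without teratoma 2. Neither scaling turned a list call. Depth limits statements on genes near 0.026 RPKM, the level of 3 reads at the median length.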

Other observations

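Of the tests given here, the host skin test was fixed before its result was seen, while the other explanations and all gene groups of this part were chosen after the results were seen. Imprinted genes went both ways. H19, IGF2 and DLK1, abundant in fetal mesenchyme and endoderm, were all highest in teratoma 1 and lowest in teratoma 3. H19 stood at 1121, 825 and 197 RPKM in teratomas 1, 2 and 3, IGF2 at 1062.0, 1044 and 180, DLK1 at 1075, 318 and 72.3, and MEG3 at 16.1, 3 and 1.24. Of 15 imprinted genes 6 were highest in teratoma 1, 2 in teratoma 2 and 7 in teratoma 3. The last were NNAT (1089, 1034 and 2718), PEG10 (74.7, 92.2 and 244), SNRPN (64.3, 73.6 and 114), NDN (98.1, 86.6 and 136), MAGEL2 (12.9, 11.5 and 21.8), GRB10 (16.5, 17.7 and 21.7) and PEG3 (1.61, 3.66 and 5.14). CDKN1C (187, 201 and 132) and PLAGL1 (16.1, 14.5 and 10.8) differed by 1.52-fold and 1.5-fold. Over the 15 the mean deviation was 0.29 in teratoma 1 and -0.3 in teratoma 3, at percentiles 99.57 and 3.15 of random lists. Genes of several neuron subtypes were present. SLC32A1, the vesicular GABA transporter, stood at 11.3, 16.3 and 38.9, SLC17A6, a vesicular glutamate transporter, at 1.98, 3.2 and 11, and TLX3 at 5.23, 5.26 and 4.75. Of genes known from cortical neurons, NEUROD2 stood at 1.31, 5.85 and 10.8, NEUROD6 at 0.41, 2.37 and 5.84, TBR1 at 4.02, 0.234 and 3.88 and SLC17A7 at 0.509, 0.308 and 0.524. CHAT, of cholinergic neurons, was at 0, 0.0723 and 0.239.

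The pancreatic genes CLPS (483, 122 and 33.2 RPKM), SPINK1 (375, 84.9 and 27.4) and the acinar factor RBPJL (16.4, 3.42 and 1.09), outside the fixed lists, were highest in teratoma 1. The plasma protein genes VTN (88.4, 267 and 18.4), HPX (1.93, 15.5 and 1.03) and AGT (9.55, 46.8 and 5.17), outside them as well, were highest in teratoma 2. A gastric group of 6 genes had mean deviations of 0.88, -0.18 and -0.7 in teratomas 1, 2 and 3. The stomach list, which also holds GKN1, had 0.32, 0.29 and -0.61, the value in teratoma 2 with a median of 0.026 and 4 of 7 members higher. Highest in teratoma 1 were the pepsinogens PGA3 (13.3, 2.65 and 0.695), PGA4 (16.4, 2.7 and 0.73) and PGA5 (14.2, 2.39 and 0.848), near-identical genes that share reads. PGC (0.0472, 0.0635 and 0.0167), ATP4A (0.128, 0.0797 and 0.129) and GKN1 (0 in each) stayed near or at 0. Of genes of stratified epithelia outside the epidermis list, the galectin LGALS7B (0.84, 16.3 and 2.53) was highest in teratoma 2, and KRT4, a mucosal keratin, in teratoma 1 (19.7, 12.2 and 4.46).

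In teratoma 3 the neuron list was higher while mesenchyme, endothelium and endoderm lists were lower. A single scale factor for the library cannot give both directions: neuron minus mesenchyme was 2.08 (SE 0.12 over genes) on the log2 scale. Dilution of all other RNA by neural RNA would lower other lists alike. It was examined over 14 lists (89 genes) whose mean deviations in teratomas 1 and 2 lay within 0.42 of each other. Changes from the mean of these libraries were taken on log2(RPKM + 0.1), which spreads low genes more than the scale used above. Only members with a mean of at least 1 RPKM entered, some through the libraries where they were high, which can widen the range. The changes ran from 1.24 (SE 0.45, 5 genes) for skeletal muscle to -2.96 (SE 0.32, 3 genes) for stomach, with -1.99 (SE 0.12, 8 genes) for endothelium. Some rested on few reads, such as MYOG with 8 in teratoma 2 and TFF2 with 9 in teratoma 3. The skeletal muscle genes include PAX7, also of dorsal neural tube, and the kidney genes include LHX1, which neurons also make. Such genes could rise with neural RNA, so the distance of these lists from the others does not count against dilution. Dealing genes across the lists gave a permutation p of 1e-05, the smallest that 100000 permutations can give. It did so too without skeletal muscle, while no run left out the kidney list. Over all 19 lists that are not neural the permutation p was the same. Those include lists that already differed between teratomas 1 and 2, such as pancreas (deviations 1.63 and -0.21). That value therefore does not bear on dilution. The permutation treats co-expressed genes as independent, but lists without neural genes that move apart as wholes are what dilution as the whole cause forbids. A lower share of mouse stroma, on the premise that stroma does not express endoderm factors, would leave these in place, and 8 of 8 were lower. The premise was not tested for any of the 8, so the result holds only as far as the premise does. For mesenchyme, endothelium and myeloid genes a lower share of mouse stroma stays open. Their drop was set against that of the endoderm factors on log2(RPKM + 0.1), over members with a mean of at least 1 RPKM. The difference was 0.161, stromal minus endoderm (SE 0.16, 28 and 8 genes). On log2(RPKM + 1), over all members, these lists deviated by -1.01, -0.75 and -0.39 in teratoma 3, and endoderm factors by -1.05. That scale understates the differences of low genes, so it does not decide the question. The human and mouse shares cannot be told apart in these data. A different mix of human tissues in the tumour or in the piece sampled may account for the pattern as a hypothesis, but the design gives 1 group and no biological explanation was tested.

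In teratoma 2 the epidermis list was higher. Host mouse skin would bring hair keratins, but the highest of 17, KRT32, stood at 0.261 RPKM there, the median at 0.04 and 0 reached 1 RPKM, while KRT1 stood at 83; this assumes that mouse hair keratin reads align to the human genome as those of KRT1 do. Loricrin, LOR, was not highest in teratoma 2 either (0.0176, 0.284 and 0.989 RPKM), whereas KRT14, which human and mouse basal epidermis both make, was higher there (0.291, 3.44 and 0.561, an excess of 1.65 on the log2 scale), as host skin would also give. Reads shared between keratins cannot carry the list, since the median deviation of its 7 members that are not keratins was 0.655, with 6 of 7 higher. Human squamous epithelium in this tumour may be the source as a hypothesis, and no biological explanation was tested.

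In teratoma 1 the pancreas list was higher. Reads shared between enzyme paralogs cannot account for the whole list, since the 7 transcription factors and hormones had a median deviation of 1.63. That 7 of 7 exceeded their mean follows from the same being true of all 11 list members. The excess was not equal among them. NKX6-1 stood at 24.8, 16.7 and 16.4 RPKM in teratomas 1, 2 and 3, and NEUROG3, at 2.38, 2.59 and 1.44, was highest in teratoma 2. Reads of IGF2 itself, by its entry with the highest mean RPKM, cannot account for the excess of INS in teratoma 1 over teratoma 2. The ratio of teratoma 1 over teratoma 2 was 13.6 for INS against 1.02 for IGF2, a quotient of 13.4. From teratoma 2 to teratoma 3 both fell, INS from 4.37 to 0.789 RPKM and IGF2 from 1044 to 180. The comparison therefore does not cover the INS values of teratomas 2 and 3. Other transcripts of the overlapping region were not examined, so whether their reads enter INS stays open. A pancreatic tissue part that differs between libraries may be the source as a hypothesis, and no biological explanation was tested.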
